A study of Solanum lycopersicum with 10 samples.

How the data were processed

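Total RNA from tomato leaves was measured on 10 two-colour cDNA arrays. Per the labels, the sample was in channel 2 of every array and a pool of all samples of the series was in channel 1. The labels name no dyes. They give 4 groups, with 3 wild type control arrays, 2 wild type systemic wounded arrays, 2 mutant control arrays and 3 mutant systemic wounded arrays. The mutant carries an antisense copy of an Rboh gene, which encodes a respiratory burst oxidase homolog, an NADPH oxidase that makes reactive oxygen species. Control leaves came from unwounded plants and systemic wounded leaves from wounded plants. Arrays are named here by the replicate numbers of their titles. The mutant control arrays are replicates 2 and 3 in their titles and 1 and 2 in their descriptions. Nothing in the labels says that replicates came from separate plants, so the p-values measure the spread between these arrays, which may be technical.

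The deposited values were log2 ratios, as their form shows: between 99.7% and 100.0% of the values per array were the log2 of a ratio rounded to 3 decimals, within a tolerance of 0.02 thousandths of the ratio. The array medians of the deposited log2 values lay between -0.01 and 0.07. Their interquartile ranges ran from 0.39 to 0.77. Whether the authors scaled the arrays to each other, the background correction and the image software are not given in the sources used here. The table held 11347 rows and 0 missing values. Of these, 193 were marked as failed quality control and 1 was a blank. Both kinds were kept out of the tests, a choice made when the row names were read and before any test was fitted, and 11153 rows were tested. Signal intensities were not analysed here, so signal over background is unknown, and the number of arrays limits the precision.

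The files do not pair the clone identifiers with gene names. Of the tested rows, 2 carry a gene name in place of a clone identifier, and 0 clone identifiers matched the RefSeq gene table (assembly SLM_r2.1). For this reason 18 gene lists fixed before the data were examined had 0 matching rows each, and no list test was run. They covered the Rboh target, wound defence proteins, jasmonate, pathogenesis-related proteins, oxidative stress enzymes, ethylene, phenylpropanoid enzymes, photosynthesis, ribosomal proteins, chaperones, cell wall, floral MADS-box genes, water deficit, auxin, proteolysis, senescence, markers of other organs and trichome markers. The level of the antisense target and a planned check of the ratio's direction with proteinase inhibitor genes were therefore not analysed here.

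Each array was set to a median of 0 over the tested rows. One linear model with 4 group means was fitted to all 10 arrays per clone with limma 3.58.1 (lmFit and eBayes, R 4.3.3), and 7 contrasts were tested, two-sided. They were wounding in each genotype, genotype in each treatment, the interaction, and the averages of the wounding contrasts and of the genotype contrasts with equal weights. A clone is said to have risen, fallen or been called when its Benjamini-Hochberg adjusted p over the 11153 rows was under 0.05. SEs are limma's, on 6 residual degrees of freedom and 6.45 prior degrees of freedom. Sets of called clones were followed in other contrasts with fry, limma's rotation test, which asks whether a set moves on balance one way, with Benjamini-Hochberg adjustment over the 5 such tests reported. Overlaps of calls between contrasts that share arrays were set beside 100 simulations without any effect.

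Clones without a gene name were named by a rule fixed before the data were examined. At most 2 clones in each direction were named per contrast, those of largest change among the called clones whose arrays did not overlap between the groups. The 2 rows with a gene name were reported with their values whether or not they passed.

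The fit was tested on simulated data with the clones' own spread, in 5 runs with 200 of 11153 clones changed. For wounding in wild type it recovered 1.7% of the clones at a log2 change of 1 and 97.6% at a log2 change of 2. For wounding in the mutant the shares were 2.2% and 96.2%, and for wounding over both genotypes 67.0% and 99.5%. The changed clones were drawn at random and scattered independently, so these shares do not carry over to the clones that responded. Of the 86 clones called below for wounding over both genotypes, 0 were called in the mutant, at a median log2 change there of 2.17.

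The alternatives listed before the data were examined were no centring, quantile and scale normalization, limma's array weights, trend and robust eBayes, a fit to the compared groups alone, a replicate block by either numbering, a minimum change of 2-fold, an adjusted p under 0.1, each array left out, and filters on missing values. Keeping the rows marked as failed, and leaving out clones that sit at an array's commonest ratio, were added after seeing the data. Plots were drawn with matplotlib 3.10.9.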

Results

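Leaf transcripts of tomato were compared between wild type plants and plants with an antisense Rboh gene, each unwounded or wounded. The labels call the wounded samples systemic, a term for the response of a plant beyond the site of injury. The design asks how wounding changed leaf transcripts in each genotype, how the genotypes differed, and whether the response to wounding depended on the genotype. All values are log2 ratios of a leaf sample to a pool of all samples, with each array's median at 0. Correlations between arrays across clones ran from 0.19 to 0.43 for the 8 pairs within a group. They ran from -0.12 to 0.40 for the 12 pairs of 1 genotype in different groups, and from -0.43 to 0.45 for the 25 pairs of different genotype. Clones are not independent replicates in these correlations.

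The direction of the ratio is not settled. The dyes are not named. Wild type control replicate 3 correlated at -0.33 with mutant systemic wounded replicate 1 and at -0.43 with mutant systemic wounded replicate 3. Turning all signs leaves correlations as they are, so these values bear only on whether single arrays run the other way. With wild type control replicates 1 and 2, this array correlated at 0.33 and 0.20. The range of the values leans to sample over pool, if the pool held the samples in equal parts. A transcript in 1 of 10 samples can exceed such a pool by at most a log2 ratio of 3.32, while it has no lower limit. The highest value on any array was 3.16, and the lowest was -6.35, 81.3-fold below the pool. All 10 arrays held values below -3.32 and 0 held values above 3.32. The arrays appear to run the same way, since 11 clones lay below -1 on all of them and 0 lay above 1 on all. These 11 clones also break the premise, whichever way the ratio runs, since ratios to an equal pool average 1, so the argument from the range is weak. Directions below are for sample over pool, and each comparison is also given with the sign turned.

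Wounding raised 30 clones in wild type leaves, with a median log2 change of 4.27 and a range from 1.45 to 5.98. Of these, 20 changed at least 8-fold and 16 at least 16-fold. Clone cLED4L7 rose most, from a mean of -3.53 ± 1.54 (SD, n = 3) in controls to 2.45 ± 0.23 (SD, n = 2) in wounded plants. Its log2 change was 5.98 (SE 0.79, limma adjusted p = 0.0139), 63.1-fold. Clone cLET19N9 rose from -4.65 ± 0.60 (SD, n = 3) to 1.05 ± 0.01 (SD, n = 2), a log2 change of 5.71 (SE 0.69, limma adjusted p = 0.0123).

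No clone fell in wounded wild type leaves by limma's adjusted p, beside 318 lower and 435 higher clones at an unadjusted p under 0.05. Chance alone gives 557.6 in both directions. With the sign turned, the split is 0 higher and 30 lower. All 30 called clones had arrays that did not overlap between the groups, as did 20.3% of all clones, where chance gives 20%. The 2 rows with a gene name did not pass. Carbonic_anhydrase, named for an enzyme that interconverts carbon dioxide and bicarbonate, had a log2 change of -0.16 (SE 0.24, adjusted p = 0.979). Chlorophyla/bbindingprotein, named for a light-harvesting protein of chloroplasts, had a log2 change of -0.85 (SE 0.32, unadjusted p = 0.0189, adjusted p = 0.555). Without wild type systemic wounded replicate 1 or 2, cLET19N9 had a log2 change of 5.71 or 5.70 and cLED4L7 one of 5.82 or 6.14. Either fit leaves 1 array in that group, so a lower count there may reflect lost power. The count of called clones moved with the arrays kept. It was 0 without either wild type systemic wounded replicate 1 or replicate 2, 4 without wild type control replicate 2, and 16 (9 higher, 7 lower) without wild type control replicate 1. It was 48 without mutant control replicate 2 and 48 without mutant control replicate 3. Leaving out either mutant control is the same check for this contrast, since the array that remains adds nothing to the estimate of the spread. Quantile normalization gave 63 calls, 55 higher and 8 lower, and scale normalization gave 7, all higher.

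In the mutant, no single clone passed for wounding, with a smallest limma adjusted p of 0.105. At an unadjusted p under 0.05 there were 310 clones, 242 higher and 68 lower, where chance gives 557.6. Of all clones, 15.2% had arrays that did not overlap between the groups, where chance gives 20%. Fewer small p-values than chance gives can mean that the p-values are too large. The 0 calls therefore do not show that no clone responded. The clones that rose in wild type still leaned the same way: 29 of the 30 were higher in wounded mutant leaves, with a median log2 change of 1.71 (limma's fry, adjusted p = 0.021). For cLET19N9 the mutant mean was -3.51 ± 2.06 (SD, n = 2) in controls and 0.46 ± 0.87 (SD, n = 3) in wounded plants, a log2 change of 3.97 (SE 0.69, adjusted p = 0.187). For cLED4L7 it was -4.30 ± 0.95 (SD, n = 2) and -2.80 ± 1.19 (SD, n = 3), a log2 change of 1.50 (SE 0.79, adjusted p = 1).

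The mutant controls were far apart at such clones. On mutant control replicate 2, cLET19N9 stood at -4.96, and on replicate 3 at -2.05. Without mutant control replicate 3, 39 clones passed, all higher, and 12 of them were among the 30 of wild type. This leaves 1 mutant control array, which is then assumed to vary like the other groups. Quantile normalization gave 25 calls and scale normalization 1, all higher. A replicate block gave 7 calls by title number and 18 by description number, all higher. All these calls become lower when the sign is turned.

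Over both genotypes, wounding raised 86 clones and lowered none. The median log2 change was 2.38, from 0.87 to 4.84, and 28 clones changed at least 8-fold. All 86 had a higher mean in wounded leaves of each genotype, with medians of 2.50 in wild type (limma's fry, adjusted p = 0.0125) and 2.17 in the mutant (adjusted p = 0.0175). By limma, 27 of them were called in wild type and 0 in the mutant, and 85 and 76 had an unadjusted p under 0.05. Neither the shared direction nor the fry p-values are independent of how the clones were chosen, by the average of both changes. Clone cLET19N9 had a log2 change of 4.84 over both (SE 0.49, limma adjusted p = 0.00171). Clone cLET21I5 rose by a log2 change of 4.78 (SE 0.56, adjusted p = 0.00368). Its means were -5.10 ± 0.72 (SD, n = 3) and 0.57 ± 0.14 (SD, n = 2) in wild type, and -3.65 ± 2.71 (SD, n = 2) and 0.25 ± 0.42 (SD, n = 3) in the mutant, controls first.

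**Figure D1:**
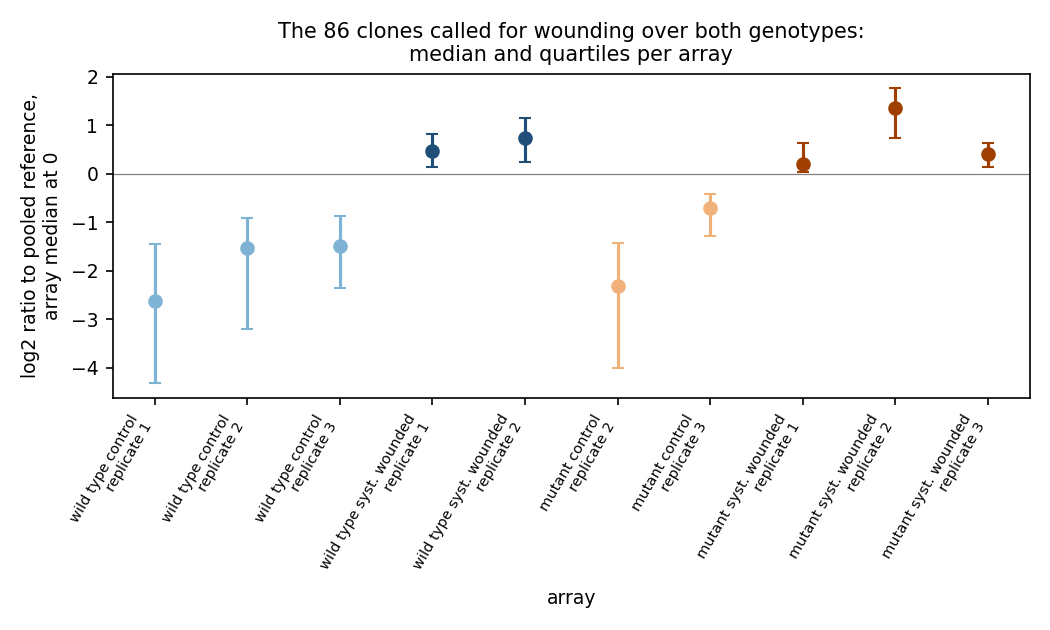
Median (points) and quartiles (bars) of the log2 ratio to the pool over the 86 clones called for wounding over both genotypes, for each of the 10 arrays, with each array's median over all clones at 0. The wounded arrays have medians from 0.20 to 1.35, wild type controls lie at -1.50 and below, and the mutant controls are at -2.31 and -0.71.

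Of the 86 clones, 70 had wounded and unwounded arrays that did not overlap. Over all clones this share was 1.63%, where chance gives 0.794%. Carbonic_anhydrase had a log2 change of -0.10 and Chlorophyla/bbindingprotein one of -0.62 (adjusted p = 0.553), and neither passed. Turning the sign makes the split 0 higher and 86 lower. By limma at an unadjusted p under 0.05, 436 clones were higher and 235 lower, and quantile normalization called 115 higher and 9 lower. The count was 30 without mutant control replicate 2, 49 without mutant systemic wounded replicate 2, 36 without wild type systemic wounded replicate 1 and 10 without wild type systemic wounded replicate 2.

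The effect of genotype on the wounding response was tested directly. No clone passed for this interaction, with a smallest limma adjusted p of 1, and 266 clones had an unadjusted p under 0.05, where chance gives 557.6. Both counts stay as they are when the sign is turned. As for wounding in the mutant, the p-values may be too large, so 0 calls do not show that no response differed. The count of calls was 1 without wild type control replicate 3. Clone cLED4L7 had an interaction of -4.48 (SE 1.11, unadjusted p = 0.00155, adjusted p = 1), meaning a smaller rise in the mutant. Clone cLED11M5 had one of -4.35 (SE 1.30, unadjusted p = 0.00551, adjusted p = 1). Over the 86 clones the median interaction was -0.33 (limma's fry, adjusted p = 0.615). Over the 30 clones that rose in wild type it was -1.57, with 29 of the 30 below 0 (limma's fry, adjusted p = 0.0727). Those 30 were chosen for a large wild type change, which by itself draws the interaction below 0. Across all 11153 clones, the wounding changes of the genotypes, which share no arrays, correlated with Pearson's r = 0.50 and Spearman's rho = 0.19. Over the 100 ways to reassign wounding within each genotype, which keep the correlation between clones, the real r was the highest, and the others ran from -0.491 to 0.467.

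**Figure D2:**
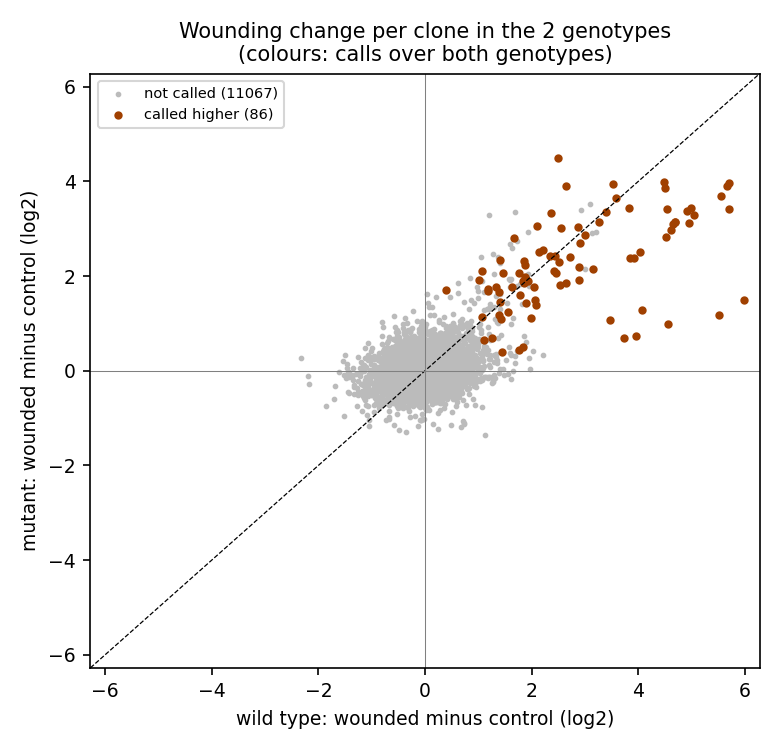
Log2 change with wounding in wild type (x axis) and in the mutant (y axis) for each of the 11153 clones, with the 86 clones called over both genotypes in colour and equality as a dashed line. All 86 lie above 0 on both axes, and the clones with the largest wild type changes lie below the line.

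Unwounded leaves of the mutant and wild type differed at 55 clones. In the mutant 40 were higher, with a median log2 difference of 1.75, and 15 were lower, with a median of -2.10. With the sign turned, 15 were higher and 40 lower. Clone cLED6G20 was at 0.87 ± 0.60 (SD, n = 2) in the mutant and -2.26 ± 0.09 (SD, n = 3) in wild type, a difference of 3.13 (SE 0.30, limma adjusted p = 0.0016). Clone cLED6A13 differed by 2.77 (SE 0.36, adjusted p = 0.00989). In the other direction, cLED11F18 was at -1.95 ± 0.08 (SD, n = 2) in the mutant and 1.18 ± 1.05 (SD, n = 3) in wild type, a difference of -3.13 (SE 0.53, adjusted p = 0.0247). Clone cLES2B19 differed by -3.07 (SE 0.56, adjusted p = 0.0319). These last calls were not firm: that of cLES2B19 was lost in 11 of 20 other settings or left-out arrays, with an adjusted p of up to 0.238, and that of cLED11F18 in 8 of 20, with up to 0.209. Carbonic_anhydrase differed by 0.09 and Chlorophyla/bbindingprotein by 0.42 (adjusted p = 0.586), and neither passed.

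All 55 clones had arrays that did not overlap between the genotypes, as did 29.2% of all clones, where chance gives 20%. The count was 6 without mutant control replicate 2, 14 without mutant control replicate 3, 30 without wild type control replicate 1 and 9 without wild type control replicate 3. It was 5 with trend and robust eBayes and 1 when the unwounded arrays were fitted alone.

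Wounded leaves differed between the genotypes at 75 clones, 47 higher and 28 lower in the mutant, with medians of 1.71 and -2.06. With the sign turned, 28 were higher and 47 lower. Of the 4 clones named for unwounded leaves, 2 passed again: cLED6A13 differed by 3.66 (SE 0.36, limma adjusted p = 0.00121) and cLED6G20 by 3.47 (SE 0.30, adjusted p = 0.0005). The values of cLED11F18, -2.21 (adjusted p = 0.0978), and cLES2B19, -2.34 (adjusted p = 0.0944), did not pass. The largest differences in the other direction belonged to wounding clones. Clone cLED4L7 was 38.1-fold lower in the wounded mutant, a log2 difference of -5.25 (SE 0.79, adjusted p = 0.0173). Clone cLED11M5 was at -2.95 ± 0.98 (SD, n = 3) in the wounded mutant and 1.98 ± 0.02 (SD, n = 2) in wounded wild type, a difference of -4.93 (SE 0.92, adjusted p = 0.0324), a call lost in 6 of 20 other settings or left-out arrays. Unwounded, cLED4L7 differed by -0.78 (adjusted p = 0.70) and cLED11M5 by -0.58 (adjusted p = 0.821).

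**Figure D3:**
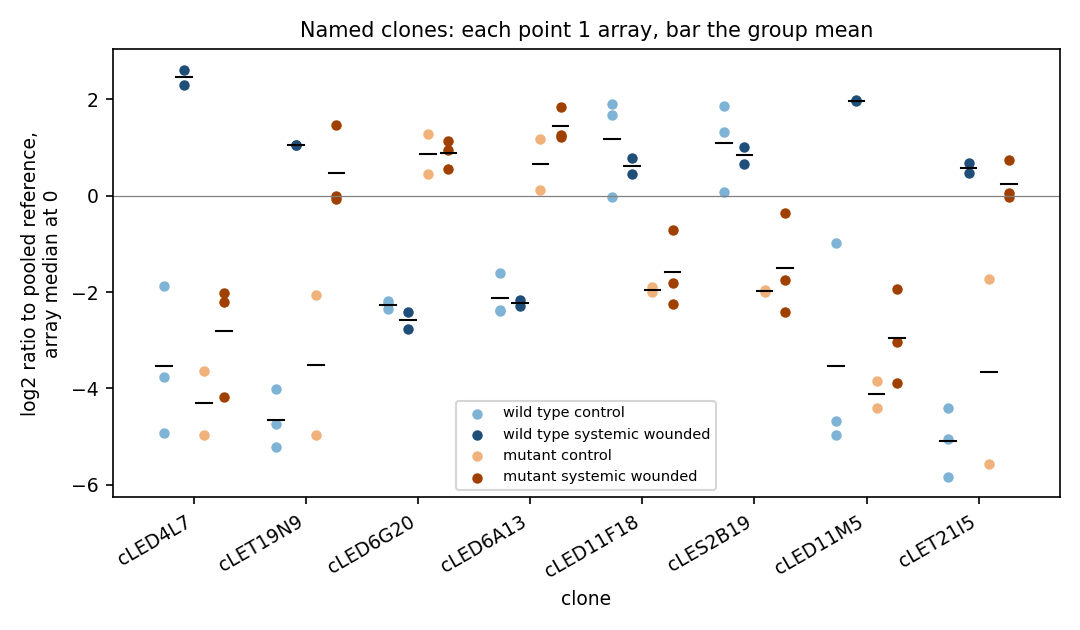
Log2 ratio to the pool, with each array's median at 0, of the 8 named clones, with a point for each array, a colour for each group and a bar at the group mean. Clones cLED4L7 and cLED11M5 are above 0 on the wild type systemic wounded arrays and below 0 on all others, while cLED6G20 and cLED6A13 separate the genotypes in both treatments.

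Of the clones that rose in wounded wild type, 6 were also lower in the wounded mutant. Both comparisons use the wild type wounded arrays, and lists of the same lengths in simulations without any effect shared 5.46 on average and 10 at most. The count of 6 alone is therefore no evidence beyond shared arrays, and it does not show that these clones come from them. Independent lists would share 0.0753. Chlorophyla/bbindingprotein differed by 0.89 (SE 0.32, unadjusted p = 0.0152, adjusted p = 0.26) and Carbonic_anhydrase by 0.21 (adjusted p = 0.765), and neither passed. All 75 clones had arrays that did not overlap, as did 33.9% of all clones, where chance gives 20%. The count was 10, 26 and 11 without mutant systemic wounded replicates 1, 2 and 3, and 3 and 1 without wild type systemic wounded replicates 1 and 2. It was 136 without wild type control replicate 3. Quantile normalization gave 152, array weights 220 and trend and robust eBayes 29.

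Genotype over both treatments was the largest contrast by count, with 343 clones higher and 156 lower in the mutant, at median log2 differences of 1.04 and -0.96. With the sign turned, 156 were higher and 343 lower. Clone cLED6G20 differed by 3.30 (SE 0.21, limma adjusted p = 1.55e-05) and cLED6A13 by 3.22 (SE 0.25, adjusted p = 0.000102). Clone cLES2B19 differed by -2.71 (SE 0.39, adjusted p = 0.00328) and cLED11F18 by -2.67 (SE 0.38, adjusted p = 0.00265). Carbonic_anhydrase differed by 0.15 and Chlorophyla/bbindingprotein by 0.65 (adjusted p = 0.113), and neither passed.

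The genotype calls of the treatments overlapped, although they share no arrays. Of the 40 clones higher in the unwounded mutant, 21 were also among the 47 higher in the wounded mutant, where independent lists would share 0.169. Lists of the same lengths shared at most 5 in the other 99 of the 100 ways to reassign genotype within each treatment. Of the 15 lower clones, 6 were shared, against 0.0377 for independent lists, but 1 of the other ways shared 7. Across all clones, the genotype differences correlated with Pearson's r = 0.62 and Spearman's rho = 0.58. The r of the other ways ran from -0.609 to 0.552. Of the 499 called clones, 398 had arrays that did not overlap between the genotypes, as did 8.63% of all clones, where chance gives 0.794%. The count was 156 and 219 without mutant control replicates 2 and 3, 276 and 233 without mutant systemic wounded replicates 1 and 3, and 105 and 179 without wild type systemic wounded replicates 1 and 2. At a minimum of 2-fold it was 254.

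**Figure D4:**
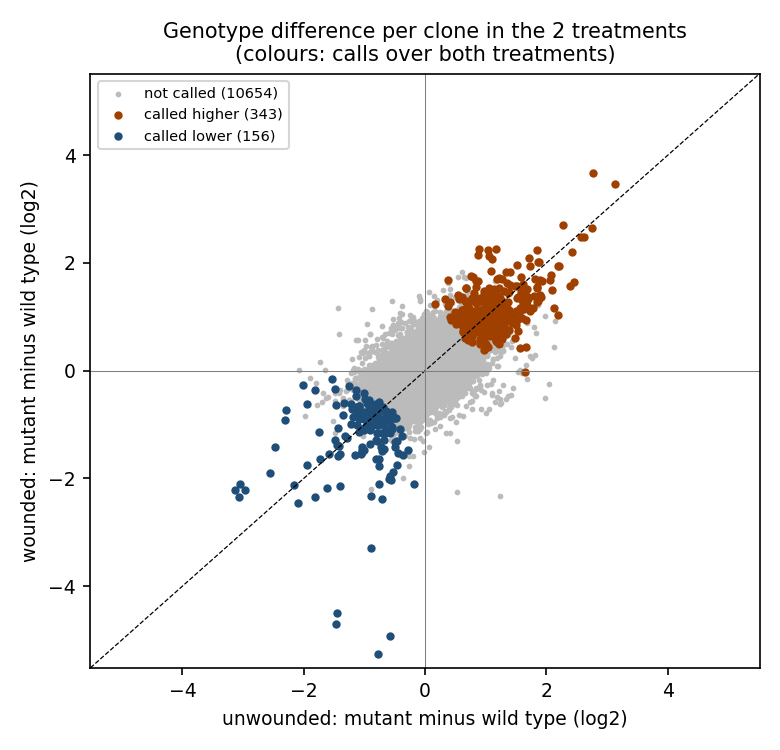
Log2 difference between mutant and wild type in unwounded (x axis) and wounded leaves (y axis) for each of the 11153 clones, with clones called over both treatments in colour and equality as a dashed line. The 343 clones called higher and the 156 called lower lie along the line, and 4 clones lie far below it, at least 16-fold lower in the wounded mutant.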

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

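Rows marked as failed quality control were outside the main comparisons, and their values were tested only after the data had been seen, by adding the 193 rows to the fit. Of these rows, 2 passed for genotype in wounded leaves (1.04%, beside 0.672% of the clones). For wounding over both genotypes, 1 passed (0.518%, beside 0.726%). For genotype over both treatments, 8 passed (4.15%, beside 4.39%). In the other contrasts, 0 passed. The blank row had a log2 change of 0.01 for wounding over both genotypes (limma adjusted p = 0.999) and -0.17 for genotype over both treatments (adjusted p = 0.569). No explanation was tested for these rows.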

How the results depend on the processing

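The tests of kept failed rows and of clones at a commonest ratio were chosen after seeing the data, and neither moved a count by over 1.5 times. No named clone changed sign: 143 of 154 values under other settings and 134 of 160 with an array left out kept the call, and the cause of the lost calls was not tested.

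For wounding in wild type, 30 clones became 63 with quantile and 7 with scale normalization, 65 with array weights, 11 with trend and robust eBayes and 70 at an adjusted p under 0.1. Leaving out arrays gave 0 to 48. For wounding in the mutant, 0 became 25 with quantile and 1 with scale normalization, and 0 to 39 with an array left out. For genotype in unwounded leaves, 55 became 5 with trend and robust eBayes, 1 in a fit to those groups alone, 96 at an adjusted p under 0.1 and 6 to 66 with an array left out. For genotype in wounded leaves, 75 became 152 with quantile normalization, 220 with array weights, 29 with trend and robust eBayes, 119 in a fit to those groups alone, 151 at an adjusted p under 0.1 and 1 to 136 with an array left out. The interaction count was 0 to 1 with an array left out and 0 otherwise. Wounding over both genotypes gave 10 to 111 with an array left out. Genotype over both treatments gave 254 at a minimum of 2-fold, 1017 at an adjusted p under 0.1 and 105 to 615 with an array left out. Where an array left out came from a group of 2, the remaining array was assumed to vary like the others. The correlation of wounding changes was 0.422 with quantile normalization and 0.396 to 0.530 with an array left out. That of genotype differences was 0.496 to 0.646. Beyond the construction of thresholds, the cause was not tested.

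The title numbers do not pair the arrays, and the description numbers do so at most in part. By title, 3 of 12 same-numbered pairs of deviations correlated above 0.1 (r from -0.352 to 0.34), and 0 of 10 arrays correlated best with its own number. By description these were 5 of 13 pairs and 5 arrays. Among the mutant control, mutant wounded and wild type control groups, arrays of number 1 correlated at 0.34 to 0.394. Those of number 2 correlated at 0.07 to 0.34. The wild type wounded arrays correlated at -0.352 to -0.111 with arrays of their own number, and the number 3 arrays at -0.156. With the number 1 arrays of the other groups, wild type systemic wounded replicate 2 correlated at 0.111 to 0.35. Replicate 1 of that group correlated at 0.113 to 0.352 with the number 2 arrays. Blocks of arrays across all groups, with these 2 numbers exchanged, are therefore not excluded, and no such block was fitted. Deviations in a group of 2 arrays mirror each other, so these values are not independent. The cause was not tested. With the title number as a replicate block, the calls were 7 for wounding in the mutant, 17 and 36 for genotype in unwounded and wounded leaves and 279 for genotype over both, with a wounding correlation of 0.546. With the description number as a replicate block, they were 62 for wounding in wild type, 18 for wounding in the mutant and 25 for genotype in unwounded leaves, with correlations of 0.391 for wounding and 0.534 for genotype.

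Filters on missing values were not run, since 0 values were missing, and neither were the gene list alternatives, since 0 rows matched. Signal over background is unknown here.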

Other observations

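The tests of the prefixes, of source plates, of mutant control replicate 3, of the spread of cLED clones and of the mutant's count were chosen after the results were seen. For mutant control replicate 3, the bounds for compressed ratios as the whole cause and for wounded wild type RNA were rewritten with the values known. Under the earlier bounds both were undecided.

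Clone identifiers begin with a prefix, and the calls were uneven across prefixes. Fisher's exact tests were run for 64 pairs of a call list and a prefix. Prefix cLEC made up 107 of the 343 clones higher in the mutant over both treatments (31.2%, beside 19.8% of clones, adjusted p = 1.32e-05) and 17 of the 156 lower ones (10.9%, adjusted p = 0.035). Prefix cLEG made up 7 of the 343 (2.04%, beside 7.9%, adjusted p = 7.47e-05). With the sign turned, the 343 clones are the lower ones in the mutant and the 156 the higher ones. Prefix cLER made up 0 of the 86 wounding clones, beside 7.27% of clones (adjusted p = 0.0248). These tests treat clones as independent.

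A chance split of the arrays is argued against for the averaged contrasts, provided that the arrays are independent replicates, which the labels do not say. With 100 ways to split, 1 of 100 is the smallest share this test can give. Of the 100 ways to reassign wounding within each genotype, 1 gave as many clones as the real one, itself, with 86 clones, and the highest other gave 20. Of the 100 ways to reassign genotype within each treatment, 1 gave 499 clones, the real one, and the highest other gave 6.

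Mutant control replicate 3 lay between the controls and the wounded arrays at the 86 wounding clones, with a median of -0.71 beside -2.31 on mutant control replicate 2. The 95% intervals in this paragraph come from drawing clones again on the same arrays, as if clones were independent. They hold no spread between arrays or plants, so what follows is limited to these arrays. Compressed ratios are argued against as the whole cause, by a bound set with the values known. At 21 clones lower in the wounded mutant by a fit without the mutant controls, the median of replicate 3 was 0.79 times that of replicate 2 (bootstrap 95% interval 0.552 to 1.22). At the wounding clones it was 0.307 times (0.23 to 0.425). The 21 clones had a median of only -0.87 on replicate 2. At 12 other clones, below -1 on all arrays but the mutant controls, the medians were -2.99 on replicate 2 and -2.47 on replicate 3, or 0.828 times (0.664 to 1.18). Clones this low whatever the sample break the premise of an equal pool, as said above. They may therefore not show how differences between samples are compressed. A stricter bound, on the interval at the 32 higher clones given below, would leave compression as the whole cause open. Wounded wild type RNA in the sample is argued against too, since the 6 clones high in wounded wild type alone lay below the level its share would give, by a median log2 gap of -3.24 (-4.14 to -1.61), or, with the ratio's sign turned, on the same side by -1.24 (-2.20 to -0.59). Compression as a part of the cause stays open: this array had the narrowest spread of the 10 (SD 0.363, beside 0.520 on replicate 2), the share was 0.589 (0.173 to 6.74) at 32 clones higher in the wounded mutant by the same fit, and, with this array in the fit, 0.605 (0.522 to 0.726) at 340 clones higher in the mutant but 1.02 (0.868 to 1.15) at 149 lower ones. A share of wounded mutant RNA stays open, at a median of 25.2% with residuals spread 0.632 times as widely as the most different pair of wounded mutant arrays, or 70.2% and 1.17 times with the sign turned, and so does a plant whose wound response was partly on without treatment, which was not tested.

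That the mutant had 0 wounding calls and wild type 30 may rest in part on this array. Without it the mutant had 39 calls, 35 of them among the 86, and without any other single array it had 0, but with all arrays kept quantile normalization gave 25. A replicate block, also with all arrays kept, gave 7 calls by title number and 18 by description number. A smaller response in the mutant can neither be shown nor excluded. Over the 86 clones, chosen by a contrast independent of the interaction, the mean change was 2.87 in wild type and 2.27 in the mutant. The mean interaction of -0.60 had a 95% interval from -2.80 to 1.59 on 6 residual degrees of freedom.

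Prefix cLED made up 54 of the 86 wounding clones (62.8%, beside 22.5% of clones; adjusted p = 7.04e-14). A shift of whole source plates, read from the number in the identifier, is argued against. With each plate's median taken off every array, 53 of the 54 stayed called, at a median change of 2.29 beside 2.31 before (SD 0.87 among them). An effect of positions within plates was not tested. Wider scatter of cLED clones is argued against as well, since their median residual SD was 1.02 times that of other clones. Several clones of 1 transcript may sit under this prefix, which stays open because clone sequences were not analysed here, and the source of the library remains an untested hypothesis.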
